A study of Homo sapiens with 8 samples.

How the data were processed

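The 8 samples were total RNA from HT29 colon cancer cells, hybridised to Affymetrix U133 Plus 2.0 arrays per the series design text. They formed 4 groups of 2 arrays: untreated adhered cells and adhered cells with 6 µM fenretinide, each at 48 h and 72 h, and untreated spheres and spheres with 3 µM fenretinide, each at 24 h and 48 h, per the labels' titles. The deposited table holds log2 values for 54675 probe sets, 1 column per array, and the submitters' processing notes name RMA, the robust multi-array average, with no version. The log base was read from the range of the values, and the sorted values of the arrays differ by at most 0.128, as after quantile normalization. Nothing in the sources used here gives the array batches, scan dates or whether the arrays came from separate cultures. Values before background correction were not used, so signal over background is unknown. All 8 columns were named by the sample's own identifier and matched by it, and the titles gave the groups and hours.

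Probe sets were named from the platform annotation supplied with the data. Of the probe sets, 41097 were listed with 1 gene symbol, 1801 with several and 11777 were not listed, and only the first kind was used. For a gene with several probe sets the one with the highest mean over the 8 arrays was kept, which gave 19775 genes. Of the probe sets chosen, 4728 end in _s_at or _x_at, classes that can bind several transcripts or genes. A gene was tested when its probe set was above the median of all values (4.57) in at least 2 arrays, which left 13120 genes. No genome was given, so no positions are reported.

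A linear model was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). It had a mean for each of the 4 groups and a difference between hours for each culture as a block, which left 2 residual degrees of freedom, with 3.91 prior degrees of freedom added by eBayes. The error of a treatment effect is therefore how far that effect differed between the 2 hours of a culture, pooled over both cultures. Comparisons were fenretinide in adhered cells, fenretinide in spheres, untreated spheres against untreated adhered cells at 48 h, the difference and the mean of the 2 treatment effects, and the hours within each culture. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. A gene called 2-fold changed had a log2 change of at least 1. Counts of genes changed in a single pair used no test.

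Before the data were examined, 30 gene lists with 631 distinct genes were fixed, of which 578 are named in the table and 516 were tested. They were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 30 lists of a comparison, then with an estimated correlation and with fry. No list call held with an estimated correlation in any comparison, where the smallest adjusted p was 0.363. That version rests on 2 residual degrees of freedom, so hardly any list could pass it. Its p-values therefore do not decide whether a list call holds. The camera p-values at the preset correlation hold only if the genes of a list are as weakly correlated as that. With fry, 1 of the 30 lists passed in adhered cells, 5 in spheres and 12 for the mean effect. For untreated spheres, the difference and both hours 0 passed. The cell type lists hold genes that colon cancer cells can express themselves. The named genes are, by a rule fixed before the data were examined, the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with the same direction in both pairs (for spheres against adhered cells, with both sphere arrays on the same side of both adhered arrays), 5 and 5 for the difference, the mean effect and the hours, where too few genes passed and the next by size with the same direction in both pairs are given as values, and from each list up to 4 members with the largest change, or more where a group is described.

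Alternatives were quantile normalization, centring each array on its median, no filter and a stricter filter (above 6.47 in 2 arrays), the mean of a gene's probe sets, only probe sets not ending in _s_at or _x_at, a variance trend, no hour block, only the arrays of a comparison, leaving out each array in turn, and a fold minimum. One alternative, the gene lists without the treated 48 h sphere array, was added after the data were seen. The steps were tested on simulated data with 13120 genes and, per comparison, 67, 67 and 66 genes changed by 3 sizes. Noise was independent between genes and had each gene's spread after moderation by eBayes, which varies less between genes than the residual spread. The shares recovered may therefore be higher than in the real data. For fenretinide in adhered cells 98.5% of changes of 2-fold and 44.8% of changes of 1.41-fold were recovered, and for the difference of effects 95.5% and 16.4%. In the real data 0 genes passed for the difference, although IFI44L differed 10.3-fold (adjusted p = 0.0803 by limma). The simulated shares therefore do not hold for that comparison, and the lack of calls does not show that differences of 2-fold were absent. In these simulations between 15 and 22 unchanged genes were called per comparison (22 of 184 calls for adhered cells), which is above the nominal rate. A planted gene list was found in every comparison and 0 of 29 random lists were called. The simulated genes were not correlated, so this does not test camera on lists of correlated genes.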

Results

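Gene expression was measured in HT29 cells, an established line of human colorectal adenocarcinoma, with and without fenretinide, a synthetic amide of retinoic acid. The cells were grown either attached to plastic in serum-containing medium (adhered cells) or as floating spheres in a serum-free medium with B-27, epidermal growth factor and insulin. Total RNA was hybridised to 8 Affymetrix U133 Plus 2.0 arrays, 2 in each of 4 groups. Adhered cells received 6 µM fenretinide and were collected at 48 h and 72 h, whereas spheres received 3 µM and were collected at 24 h and 48 h. Each treated array had 1 untreated array of the same culture and hour, which gave 4 time-matched pairs. The 2 arrays of a group were therefore different hours and not replicates of the same hour. Nothing in the labels says that the arrays came from separate cultures, so p-values measure only the spread between these arrays. The series title poses the question addressed here, the response of colon cancer spheres and of adhered cells to fenretinide. Array medians lay between 4.53 and 4.60 on the log2 scale, and the small number of arrays limits the precision. Of 54675 probe sets, 41097 were paired with 1 gene symbol, and 13120 genes of 19775 passed the filter on low signal and were tested. All changes are log2 differences with their standard error (SE) from the limma fit.

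In adhered cells, fenretinide raised the chemokine genes CXCL2 (3.44 ± 0.28, adjusted p = 0.00602) and CXCL8 (3.43 ± 0.30, adjusted p = 0.00689) over 2 pairs. ATF3, a stress-induced transcription factor, rose 9.16-fold (3.19 ± 0.14, adjusted p = 0.00391), and AKR1C1, an aldo-keto reductase, rose 7.55-fold (2.92 ± 0.25). CDKN2B, which encodes a cyclin-dependent kinase inhibitor, rose by 2.61 ± 0.16. The largest falls were mostly in genes that interferon induces, led by IFI44L (-2.99 ± 0.24, adjusted p = 0.00602), CMPK2 (-2.75 ± 0.39), IFIT1 (-2.26 ± 0.23) and RSAD2 (-2.16 ± 0.40, with -1.39 in the 48 h pair alone). In all, 1395 genes passed an adjusted p of 0.05, of which 724 rose and 671 fell. All 1395 moved the same way in both pairs, which the test requires, since its error holds the difference between the pairs. Among them 164 rose and 90 fell by at least 2-fold.

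The other genes with the largest rises in adhered cells were GEM (2.92 ± 0.27), CLGN (2.70 ± 0.27), MAP2 (2.53 ± 0.45), the long noncoding RNA UCA1 (2.49 ± 0.20) and DUSP5 (2.46 ± 0.14), a phosphatase that acts on ERK. Falls were also seen for CD200 (-2.04 ± 0.19), IFITM1 (-1.99 ± 0.30), EPSTI1 (-1.98 ± 0.32), PDZK1 (-1.95 ± 0.28), the NADPH oxidase gene NOX1 (-1.94 ± 0.44) and the secreted lectin gene REG4 (-1.94 ± 0.11). Of these 20 genes, 8 had another probe set above the filter level, and all 12 such probe sets moved in the same direction. The other probe sets gave smaller changes for ATF3 (1.59), CDKN2B (1.05), 1 of those for AKR1C1 (0.77) and 1 of those for NOX1 (-0.70). In the 48 h pair alone the falls were smaller for IFITM1 (-1.32), EPSTI1 (-1.23) and NOX1 (-1.24). Untreated signals of CXCL2, GEM, CLGN and MAP2 and treated signals of CD200, PDZK1 and REG4 were below the filter level, so the size of their changes depends on background, as it does for IFI44L and EPSTI1 at 48 h. The probe sets of CXCL2, CXCL8 and AKR1C1 end in _x_at, and those of ATF3, CD200, IFITM1 and NOX1 in _s_at. Both classes can also bind related transcripts.

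**Figure D1:**
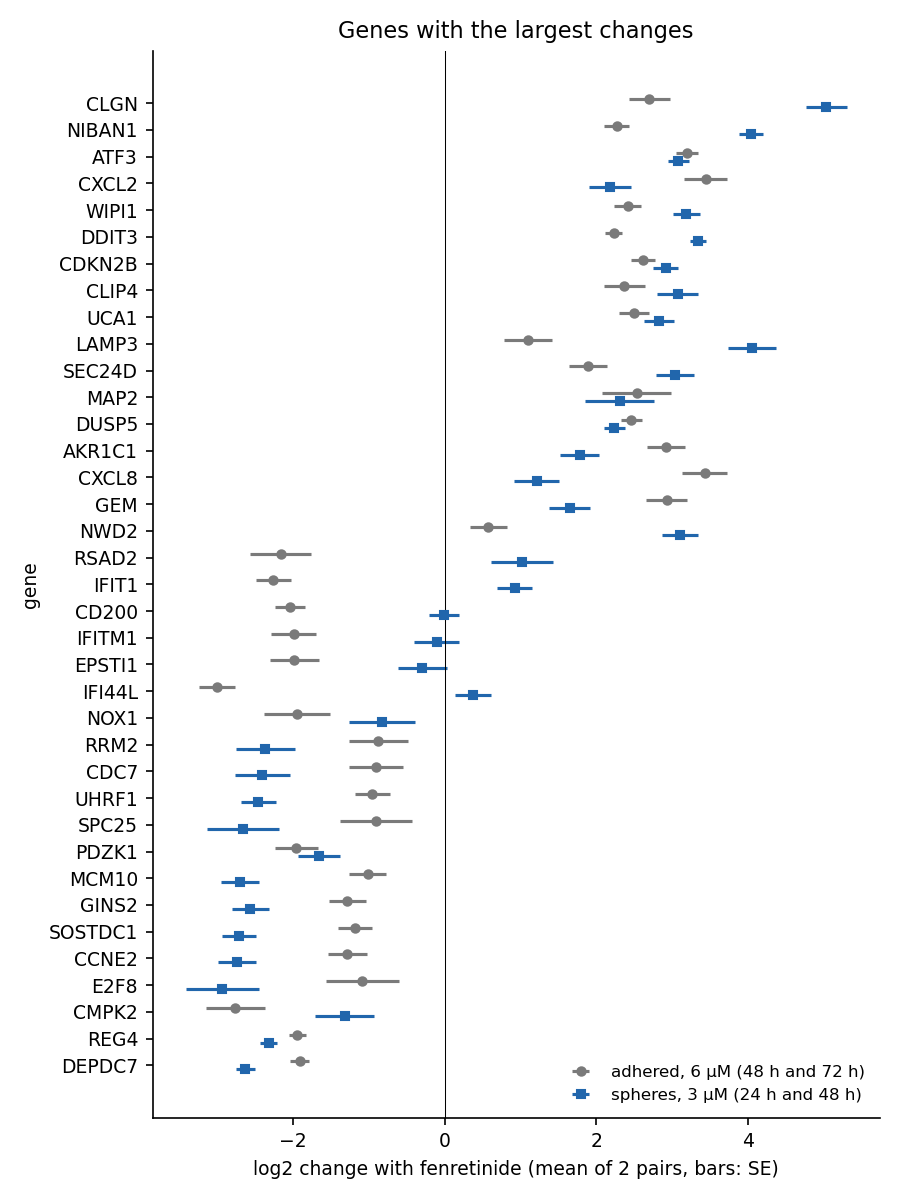
Log2 change with fenretinide (horizontal axis) of the 37 genes with the largest changes in either culture (vertical axis, ordered by the mean over both cultures); symbols are means over 2 time-matched pairs and bars are the SE of the limma fit. CLGN lies at 2.70 in adhered cells and 5.03 in spheres, whereas IFI44L lies at -2.99 and 0.38.

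Genes of the endoplasmic reticulum (ER) chaperone and degradation list rose together in adhered cells. Of its 19 tested members 16 rose (19 adjusted over the list alone), with a median of 0.81, among them the chaperone cofactor DNAJB9 (2.26 ± 0.11), HERPUD1 (1.68 ± 0.10, another probe set 0.63), HYOU1 (1.20 ± 0.09) and HSPA5, the main chaperone of the ER (1.11 ± 0.09). The camera test of this list gave an adjusted p = 7.72e-16 but adjusted p = 0.363 with an estimated correlation. Targets of NRF2, which controls the response to oxidants, had a median of 0.999, and 15 of 21 rose (19 adjusted over the list alone), including GCLM (1.61 ± 0.14) and SLC7A11 (1.56 ± 0.12). Targets of ATF4 and CHOP, transcription factors of the integrated stress response, had a median of 0.83, and 15 of 23 rose (16 adjusted over the list alone). DDIT3, which encodes CHOP, rose by 2.23 ± 0.11, PPP1R15A by 1.77 ± 0.11 and TRIB3 by 1.17 ± 0.14. In the NF-kB and inflammatory list 10 of 17 members rose (12 adjusted over the list alone, with 1 lower), among them CCL20 (1.75 ± 0.18) and NFKBIA (1.29 ± 0.16), for a median of 0.67. In the autophagy and lysosome list 8 of 22 rose (10 adjusted over the list alone), among them WIPI1 (2.41 ± 0.18), SQSTM1 (1.78 ± 0.13, with 0.35 by 1 of 3 other probe sets) and GABARAPL1 (1.64 ± 0.10). For each of these 4 lists the adjusted p was at most 8.54e-09 with the preset correlation, and adjusted p = 0.423 with an estimated correlation. The difference between the probe sets at the 3′ and 5′ ends of the actin transcript, a sign of RNA integrity, was 0.145 larger with fenretinide at 48 h and 0.269 larger at 72 h in these pairs, and that of GAPDH 0.00996 and 0.0487 larger.

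Interferon response genes were lower with fenretinide in adhered cells, with a median of -1.29 over the 23 tested members. Of these 20 fell (23 adjusted over the list alone), among them MX1 (-1.90 ± 0.20), USP18 (-1.84 ± 0.26) and IFI6 (-1.500 ± 0.25), with adjusted p = 6.67e-14 for the list and adjusted p = 0.423 with an estimated correlation. In the DNA replication list 3 of 28 members fell (12 adjusted over the list alone), namely CCNE2 (-1.28 ± 0.25), GINS2 (-1.28 ± 0.24) and POLA1 (-0.71 ± 0.14). That list had a median of -0.74 and an adjusted p = 1.93e-07, or adjusted p = 0.673 with an estimated correlation. None of the 25 genes of the G2/M and mitosis list passed the limma test, over all genes or adjusted over the list alone, although the median was -0.59 and camera gave an adjusted p = 0.00302 (adjusted p = 0.673 with an estimated correlation). The error was pooled over both cultures, so it also held the difference between the sphere pairs. Medians of the G2/M list were -0.575 and -0.59 in the adhered pairs but -0.725 and -2.465 in the sphere pairs. For DNA replication they were -0.68 and -0.851 against -1.242 and -2.608. The few or absent calls therefore do not show that these genes were unchanged in adhered cells. A second probe set of GINS2 showed no fall (-0.000762).

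Several further lists passed in adhered cells. Of 7 metallothionein and zinc genes 4 fell (7 adjusted over the list alone), with MT1X at -0.80 ± 0.19 and a median of -0.72 (adjusted p = 0.425 with an estimated correlation). Of 14 retinoic acid response genes 5 rose (5, with 1 lower, adjusted over the list alone), led by CYP26A1 (2.08 ± 0.12), which degrades retinoic acid, and RARRES1 (1.30 ± 0.19). Of 24 hypoxia genes 7 rose (11, with 2 lower, adjusted over the list alone), including ADM (1.98 ± 0.29), NDRG1 (1.501 ± 0.17) and VEGFA (0.86 ± 0.13). Of 13 Wnt targets 5 fell (7 adjusted over the list alone), including DKK1 (-1.27 ± 0.20) and ASCL2 (-1.18 ± 0.11). For these 3 lists camera gave adjusted p = 0.00095, 0.000418 and 0.00298, and adjusted p = 0.423 with an estimated correlation. Of 14 xenobiotic genes 1, CYP3A5 (0.85 ± 0.19, with 0.16 by 1 of 3 other probe sets), rose (3, with 2 lower, adjusted over the list alone; adjusted p = 0.423 with an estimated correlation). Medians of the oxidative phosphorylation and ribosome biogenesis lists were -0.22 and -0.27, with 1 of 23 and 2 of 17 members lower (0 and 2 adjusted over the list alone), and adjusted p = 0.673 and 0.477 with an estimated correlation. The other 15 lists did not pass in adhered cells: MAPK feedback, cholesterol, fatty acid synthesis, glycolysis, apoptosis, stem cell markers, heat shock, sphingolipids, p53 targets, YAP targets, integrins and laminins, absorptive cells, goblet and related cells, fibroblasts, and leukocytes with endothelium (adjusted p from 0.0698 to 0.963). The median and the mean had opposite signs for p53 targets (-0.13 and 0.08), integrins and laminins (-0.04 and 0.01), leukocytes with endothelium (0.02 and -0.06) and YAP targets (-0.00258 and 0.00357).

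The count of 1395 genes in adhered cells rested on both hours and on how the spread was estimated. Without the 72 h pair 18 genes passed and without the 48 h pair 167, whereas the 4 adhered arrays alone gave 2588 (1112 higher and 1476 lower) and a fit without the hour as a block gave 754 (471 higher and 283 lower).

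In spheres, fenretinide raised CLGN, which encodes an ER chaperone, by 5.03 ± 0.27 (adjusted p = 0.00101), LAMP3, a lysosomal membrane protein gene, by 4.05 ± 0.31 (adjusted p = 0.00183) and NIBAN1 by 16.4-fold (4.04 ± 0.16, adjusted p = 0.000838). DDIT3 rose 10.1-fold (3.34 ± 0.11, adjusted p = 0.000829). The largest falls were mostly in genes of DNA replication and the cell cycle, led by E2F8 (-2.93 ± 0.48, adjusted p = 0.00824, with -1.81 in the 24 h pair alone) and CCNE2, which encodes cyclin E2 (-2.74 ± 0.25, adjusted p = 0.00236). The untreated signals of CLGN, LAMP3 and NWD2 were below the filter level, as was that of CLIP4 at 48 h, and so were the treated signals of DEPDC7 and, at 48 h, of E2F8, CCNE2, SOSTDC1, SPC25 and CDC7, so the size of these changes depends on background. A total of 4370 genes passed, 2045 higher and 2325 lower. All 4370 moved the same way in both pairs, as they must to pass this test. Of these, 429 rose and 439 fell by at least 2-fold.

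Among the genes with the largest rises in spheres were also WIPI1, an autophagy gene (3.18 ± 0.18), NWD2 (3.10 ± 0.24), ATF3 (3.08 ± 0.14), CLIP4 (3.07 ± 0.27), the COPII coat gene SEC24D (3.04 ± 0.25) and CDKN2B (2.91 ± 0.16, another probe set 0.81). Further falls were those of SOSTDC1 (-2.71 ± 0.22), MCM10 (-2.69 ± 0.24), SPC25 (-2.66 ± 0.47), DEPDC7 (-2.62 ± 0.13), GINS2 (-2.56 ± 0.24), UHRF1 (-2.46 ± 0.23), CDC7 (-2.40 ± 0.36) and the ribonucleotide reductase gene RRM2 (-2.36 ± 0.39). In the 24 h pair alone the falls were smaller for SPC25 (-1.54), CDC7 (-1.57) and RRM2 (-1.45). For GINS2 a second probe set gave 0.04, and with only the more specific probe sets the fall was not seen. Other probe sets of these 20 genes that were above the filter level moved the same way in 10 of 11 cases.

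**Figure D2:**
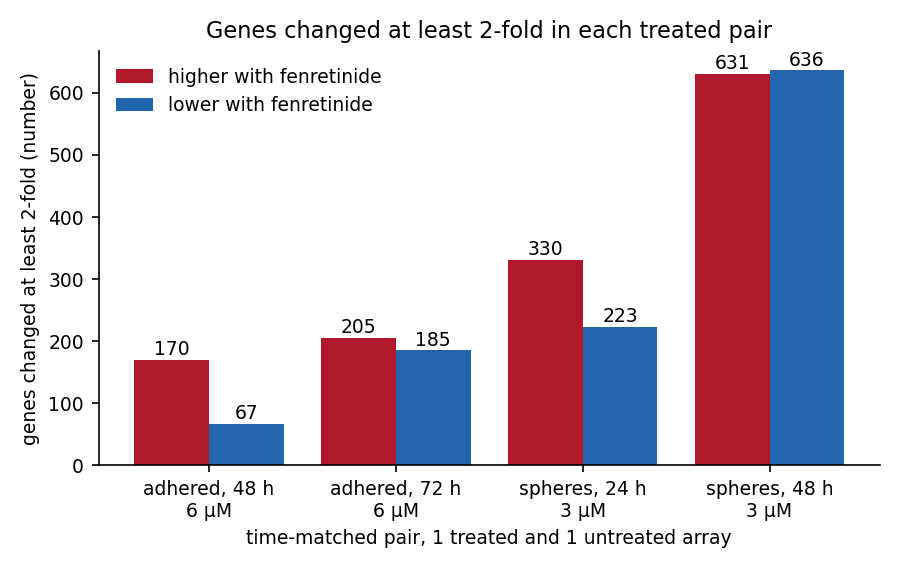
Number of genes changed at least 2-fold, up or down, in each pair of 1 treated and 1 untreated array (vertical axis, of 13120 genes; no test). The adhered pairs had 237 genes at 48 h and 390 at 72 h, and the sphere pairs 553 at 24 h and 1267 at 48 h.

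Stress response lists rose in spheres. Of 23 ATF4 and CHOP targets 22 rose (22 adjusted over the list alone), with a median of 1.38, among them CTH (2.54 ± 0.09), TRIB3 (2.35 ± 0.14), DDIT4 (2.15 ± 0.10) and SESN2 (2.12 ± 0.10). For this list camera gave an adjusted p = 3.37e-15, and adjusted p = 0.559 with an estimated correlation. All 19 ER chaperone and degradation genes rose (19 adjusted over the list alone), with a median of 0.94, including HERPUD1 (2.79 ± 0.10, another probe set 0.88), DNAJB9 (2.75 ± 0.11) and HSPA5 (1.25 ± 0.09). Their camera test gave an adjusted p = 6.66e-12, or adjusted p = 0.5 with an estimated correlation. In the autophagy and lysosome list 15 of 22 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 0.559 with an estimated correlation). Those 2 were GLA (-0.56 ± 0.16, with -0.37 in the 24 h pair alone), a lysosomal galactosidase gene, and TFEB (-0.34 ± 0.09), a transcription factor of lysosomal genes, while MAP1LC3B rose by 2.15 ± 0.13. Of 21 NRF2 targets 12 rose (13 adjusted over the list alone) and of 17 NF-kB and inflammatory genes 13 (13 adjusted over the list alone), with medians of 0.49 and 0.68 and adjusted p = 0.713 with an estimated correlation for both. LCN2 rose by 2.68 ± 0.13 and IL32 by 1.97 ± 0.30 (1.31 in the 24 h pair alone).

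Cell cycle lists were lower with fenretinide in spheres. In the DNA replication list 27 of 28 members fell (28 adjusted over the list alone), with a median of -1.96, including the helicase subunits MCM5 (-2.29 ± 0.29) and MCM6 (-2.19 ± 0.21) and, by a smaller amount, PCNA (-1.57 ± 0.18). In the G2/M and mitosis list 24 of 25 fell (25 adjusted over the list alone), with a median of -1.62, including CCNA2 (-1.98 ± 0.31), MKI67 (-1.94 ± 0.41) and CDK1 (-1.81 ± 0.35). In the 24 h pair alone these 3 were at -1.26, -0.99 and -0.98. The list medians were larger in size in the 48 h pair than in the 24 h pair, at -2.61 and -1.24 for DNA replication and -2.46 and -0.72 for G2/M. Both lists passed camera with adjusted p = 1.07e-13 and 2.22e-08, and both had adjusted p = 0.713 with an estimated correlation. Of 17 ribosome biogenesis genes 13 fell (13 adjusted over the list alone), led by UTP20 (-1.20 ± 0.12), with a median of -0.64 (adjusted p = 0.559 with an estimated correlation). The actin 3′ to 5′ difference was 0.439 larger with fenretinide at 24 h and 0.496 larger at 48 h in the sphere pairs, and that of GAPDH 0.103 and 0.0307 larger.

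Of the 23 interferon response genes, 10 rose with fenretinide in spheres (11 adjusted over the list alone) and 0 fell. Counted with no test, 5 of the 23 were lower in the 24 h pair and 4 in the 48 h pair. CMPK2, an interferon-induced gene outside the list, was lower in both sphere pairs. Its signal was 5.95 untreated and 5.26 treated at 24 h, and 5.99 and 4.04 at 48 h. IFIT2 rose by 1.88 ± 0.18 (another probe set 0.88), IFIT3 by 1.61 ± 0.21 and IFIH1 by 1.24 ± 0.23, and the list had a median of 0.64 (adjusted p = 0.00143, and adjusted p = 0.713 with an estimated correlation). Retinoic acid response genes had a median of 0.77. Of its 14 members 8 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.559 with an estimated correlation), with DHRS3, a retinal reductase gene, at 1.99 ± 0.12, PLAAT4 at 1.77 ± 0.15 and CYP26A1 at 1.02 ± 0.12, and the retinoic acid binding protein gene CRABP2 at -0.53 ± 0.12. In the hypoxia list 13 of 24 rose and 3 fell (13 and 3 adjusted over the list alone; adjusted p = 0.559 with an estimated correlation). NDRG1 rose by 1.81 ± 0.17 and VEGFA by 1.44 ± 0.13, whereas LDHA (-0.74 ± 0.14, with -0.48 in the 24 h pair alone), PFKFB3 (-0.39 ± 0.11) and HK2 (-0.36 ± 0.09), which act in glycolysis, fell. Of 16 glycolysis genes 9 fell (9 adjusted over the list alone), among them PKM (-0.81 ± 0.10, another probe set -0.12), of 23 oxidative phosphorylation genes 8 fell (8 adjusted over the list alone), and of 13 heat shock genes 7 fell and 1 rose (7 and 1 adjusted over the list alone). For these 3 lists the medians were -0.42, -0.24 and -0.36, with adjusted p = 0.713 with an estimated correlation. Of 13 Wnt targets 6 fell (7 adjusted over the list alone), with ASCL2 at -1.28 ± 0.11 (adjusted p = 0.586 with an estimated correlation). The other 15 lists did not pass in spheres (adjusted p from 0.276 to 0.943), and metallothionein genes had a median of -0.02 with 0 of 7 called. For fatty acid synthesis, integrin, p53 and MAPK genes the mean, median and test differed in sign, with no median or mean beyond 0.16 in size.

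Fewer genes passed in spheres without the 48 h pair (2061) than without the 24 h pair (3956). In both of these fits the spread came from the adhered arrays alone. Adhered and sphere pairs differed in dose and in 1 of their 2 hours as well as in culture.

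**Figure D3:**
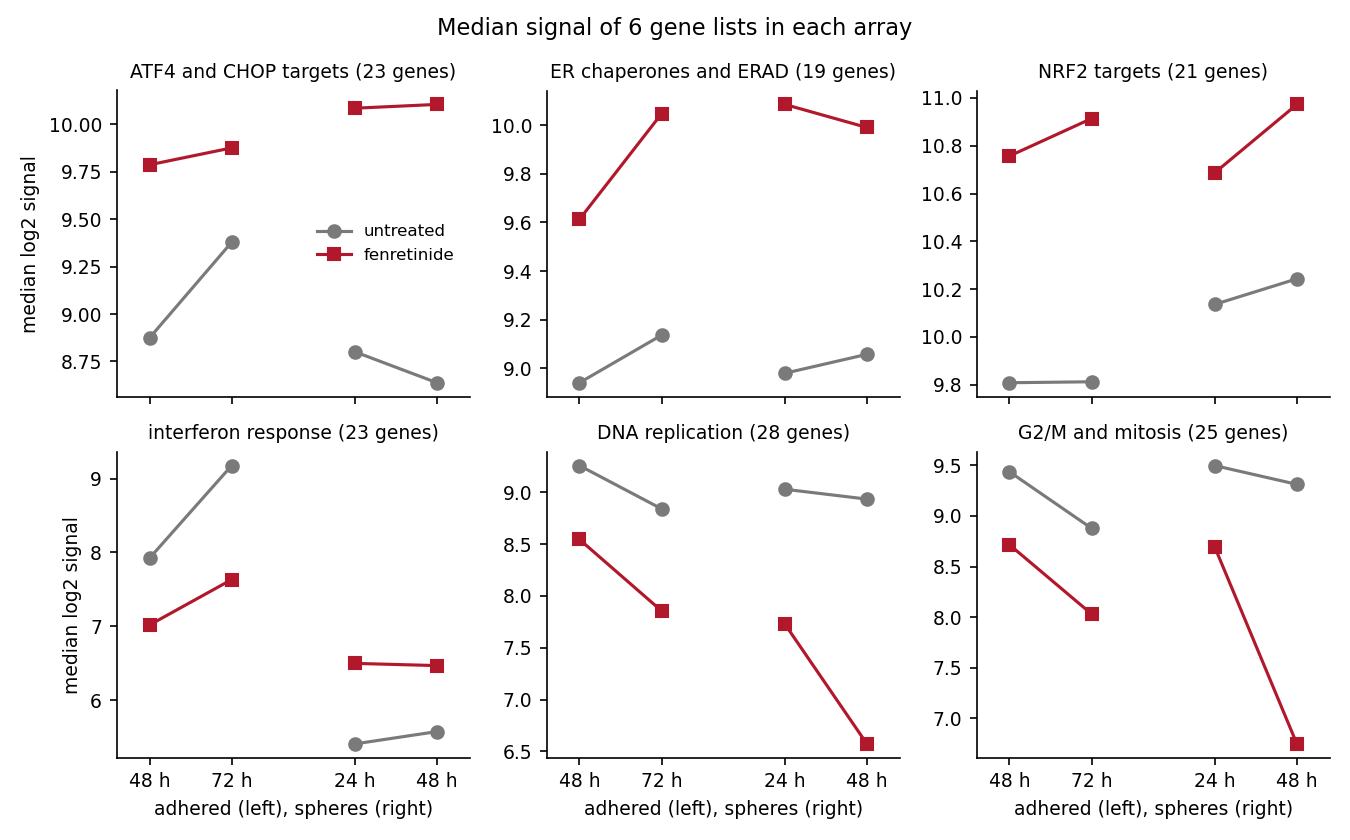
Median log2 signal (vertical axes) over the tested members of 6 gene lists in each of the 8 arrays, by hour (horizontal axes), with lines joining the 2 arrays of a group. Interferon response genes had a median of 7.92 and 9.18 in untreated adhered cells and 5.41 and 5.58 in untreated spheres.

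The 2 cultures shared much of the response. Of the genes called in both, 593 rose and 504 fell in both cultures, against 113 and 119 for independent lists, and 16 went in opposite directions. Of the 1395 genes called in adhered cells, 94.5% had the same sign in spheres. Both comparisons drew on a single estimate of each gene's spread; fitted in each culture alone, 747 rose and 964 fell in both (139 and 209 for independent lists), and 29 were opposite. Across genes, the changes of an adhered and a sphere pair correlated with r from 0.584 to 0.721 (rho from 0.544 to 0.662) over 4 combinations of hours, compared with r = 0.784 (rho = 0.681) between the 2 adhered hours and r = 0.848 (rho = 0.787) between the 2 sphere hours. Genes are not independent replicates, so no p-value is attached to these 6 correlations. Over both cultures, CLGN rose by 3.86 ± 0.19 (adjusted p = 0.000402), NIBAN1 by 3.15 ± 0.11, ATF3 by 3.14 ± 0.10, CXCL2 by 2.81 ± 0.20 and WIPI1 by 2.80 ± 0.13, while DEPDC7 (-2.27 ± 0.09), REG4 (-2.13 ± 0.08), CMPK2 (-2.03 ± 0.27), E2F8 (-2.01 ± 0.34) and CCNE2 (-2.01 ± 0.18) fell. This mean effect passed for 5017 genes, 2206 higher and 2811 lower, of which 4649 moved the same way in all 4 pairs. Without the 72 h adhered pair 2782 passed, and without the 48 h adhered pair 3002. Of 23 ATF4 and CHOP targets 22 rose (22 adjusted over the list alone; adjusted p = 0.539 with an estimated correlation), all 19 ER chaperone and degradation genes rose (19 adjusted over the list alone; adjusted p = 0.450 with an estimated correlation), and all 28 DNA replication genes fell (28 adjusted over the list alone; adjusted p = 0.679 with an estimated correlation).

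**Figure D4:**
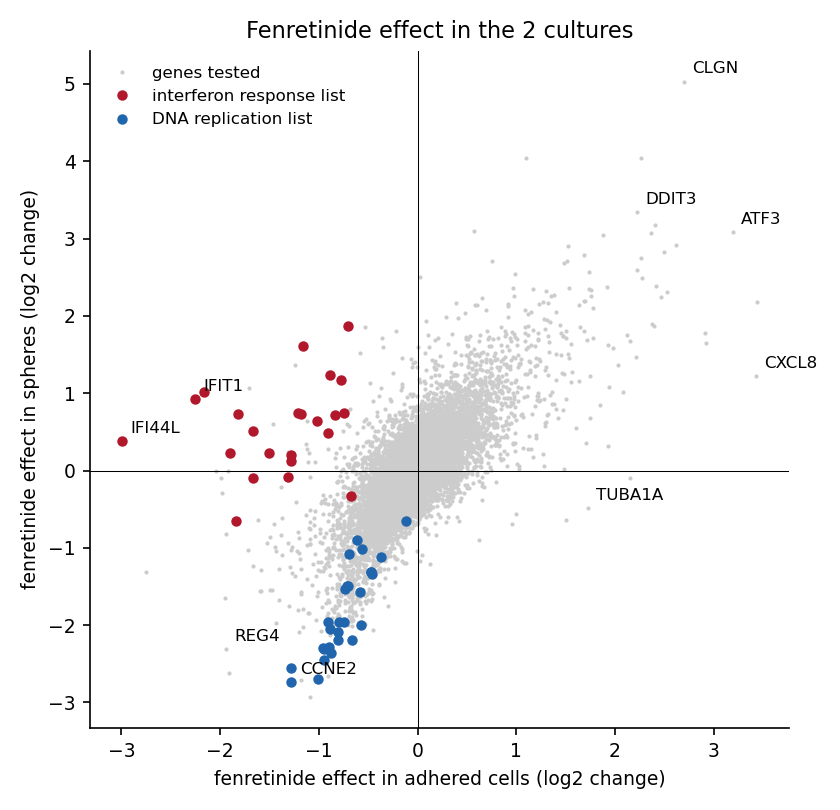
Fenretinide effect in adhered cells (horizontal axis) and in spheres (vertical axis), both log2 changes, for 13120 genes; red marks 23 interferon response genes and blue 28 DNA replication genes. IFIT1 lies at -2.26 and 0.92 (1.41 in the 24 h and 0.44 in the 48 h sphere pair), and CCNE2 at -1.28 and -2.74.

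Effects that differed most between spheres and adhered cells were those of interferon-induced genes, although no single gene passed the test of the difference. The effect in spheres minus that in adhered cells was 3.37 ± 0.34 for IFI44L (adjusted p = 0.0803), 3.18 ± 0.33 for IFIT1 (adjusted p = 0.0803), 3.18 ± 0.57 for RSAD2, 2.94 ± 0.44 for LAMP3 and 2.78 ± 0.28 for DDX60. It was -2.25 ± 0.52 for AKAP12, -2.21 ± 0.42 for CXCL8, -2.21 ± 0.21 for the tubulin gene TUBA1A (adjusted p = 0.0792), -2.14 ± 0.42 for MLLT11 and -1.84 ± 0.68 for E2F8. Signals of IFI44L in all sphere arrays, and of RSAD2, LAMP3 and DDX60 in untreated spheres, were below the filter level, so a fall in spheres could not be seen for these genes and the size of their differences depends on background. The same holds for HERC5 and XAF1 of the interferon response list, and the sizes for AKAP12 and E2F8 include 1 array each below that level. By limma 0 of 13120 genes passed, with a smallest adjusted p of 0.0767, and 2321 had an unadjusted p under 0.05. Of the 23 interferon response genes 22 passed when adjusted over the list alone, with a median difference of 1.91 (camera adjusted p = 2.36e-21, and adjusted p = 0.634 with an estimated correlation). By fry neither this list nor any other passed for the difference, with a smallest adjusted p of 0.142. In the 48 h pairs alone the list's median change was -0.94 in adhered cells and 0.52 in spheres. DNA replication genes had a median difference of -1.16, with 18 of 28 past the threshold adjusted over the list alone, and ATF4 and CHOP targets one of 0.79, with 15 of 23 adjusted over the list alone. G2/M and mitosis genes had a median difference of -1.06 with 0 of 25 adjusted over the list alone, and their median change was -0.57 and -0.59 in the adhered pairs, -0.72 in the 24 h sphere pair and -2.46 in the 48 h sphere pair. NRF2 targets had a median difference of -0.32 with 5 of 21 lower adjusted over the list alone. These lists and the other 5 that passed, glycolysis, heat shock, ribosome biogenesis, ER chaperones and metallothioneins, all had adjusted p = 0.634 with an estimated correlation. Without the 24 h sphere pair 695 genes passed, without the 48 h adhered pair 11 and without the 48 h sphere pair 1; a variance trend gave 40 and no filter on low signal 14. In the fits without a pair the spread came from the other culture alone, so those counts do not show the part of an hour. Culture, medium, dose and hour cannot be separated in this comparison.

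Untreated spheres had much lower levels of interferon-induced genes than untreated adhered cells at 48 h, the hour both cultures share. Each culture had a single untreated array at that hour. The SE and p-values of this comparison therefore hold how far the drug effect differed between hours, not the spread between untreated cultures. The fitted difference was -4.17 ± 0.28 for IFIT1 (adjusted p = 0.00757), -3.74 ± 0.36 for IFITM1, -3.51 ± 0.27 for IFI44 and -3.50 ± 0.29 for IFI44L. The fit takes the difference between hours from all arrays of a culture; the 2 untreated 48 h arrays themselves differed by -3.84 for IFIT1, -3.32 for IFITM1, -3.18 for IFI44L and -2.65 for CMPK2. LUM, which encodes the matrix proteoglycan lumican, was higher by 3.58 ± 0.17 (adjusted p = 0.0059; 3.40 between the 48 h arrays), but a second LUM probe set differed by 0.17 and stayed at or below 2.85 in all 8 arrays. The chemokine gene CCL20 was higher by 2.55 ± 0.22 (adjusted p = 0.0124) and PI3, an elastase inhibitor gene, 5.64-fold higher (2.496 ± 0.15, adjusted p = 0.00624). Signals of LUM, CCL20 and SPRR1B in untreated adhered cells and of IFI44L, DDX60 and LOXL1 in untreated spheres were below the filter level, so the size of these differences depends on background. In total 164 genes passed, 70 higher and 94 lower in spheres, of which 44 and 75 differed by at least 2-fold.

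Further genes higher in spheres were the serpin SERPINE2 (2.40 ± 0.25), CEACAM5 (2.29 ± 0.14), CDA (2.07 ± 0.20), LURAP1L (1.99 ± 0.19), the transporter SLCO1B3 (1.93 ± 0.12), TUBA1A (1.91 ± 0.18) and SPRR1B (1.86 ± 0.27). A second CEACAM5 probe set went the other way (-0.41). Lower in spheres were also MX1 (-3.31 ± 0.25), CMPK2 (-3.30 ± 0.48), IFIT3 (-3.23 ± 0.26), DDX60 (-3.22 ± 0.24), LOXL1, a lysyl oxidase family gene (-3.19 ± 0.18), and IRF9, a transcription factor of the interferon response (-3.16 ± 0.13). In the interferon response list 17 of 23 were lower (23 adjusted over the list alone), with a median of -2.28 (adjusted p = 2.15e-29, and adjusted p = 0.619 with an estimated correlation). By fry neither this list nor any other passed in this comparison, with a smallest adjusted p of 0.0866. In the NF-kB and inflammatory list 4 of 17 were higher (8, with 2 lower, adjusted over the list alone), with CXCL1 at 1.75 ± 0.15 and CXCL3 at 1.66 ± 0.14 beside CCL20 and TNFAIP3 (adjusted p = 0.652 with an estimated correlation). Of 18 cholesterol genes 0 passed over all genes and 12 were higher adjusted over the list alone, with a median of 0.45 and SQLE at 0.98 ± 0.16 (adjusted p = 0.619 with an estimated correlation). Of 23 ATF4 and CHOP targets 3, CTH (-1.10 ± 0.12), JDP2 (-1.05 ± 0.13) and DDIT4 (-1.03 ± 0.13), were lower (5, with 1 higher, adjusted over the list alone; adjusted p = 0.652 with an estimated correlation). Of 14 retinoic acid response genes PLAAT4 (-2.79 ± 0.18) and TGM2 (-1.70 ± 0.16) were lower (4 adjusted over the list alone; adjusted p = 0.619 with an estimated correlation). For TGM2, 1 of 3 other probe sets gave 0.10. Of 24 hypoxia genes 3 were higher (6 adjusted over the list alone), NDRG1 (1.498 ± 0.20), ANKRD37 (1.15 ± 0.14) and P4HA2 (1.14 ± 0.14), with adjusted p = 0.619 with an estimated correlation. NRF2 targets (median 0.34, 7 of 21 higher adjusted over the list alone), heat shock genes (0.34, 1 of 13 higher, 3 adjusted over the list alone) and ribosome biogenesis genes (0.18, 0 of 17) had adjusted p = 0.652 with an estimated correlation. Fatty acid synthesis genes (median 0.23, 3 of 12 higher adjusted over the list alone) and goblet and related genes (0.22, 0 of 13) had adjusted p = 0.619 with an estimated correlation.

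Medians of DNA replication and G2/M genes were -0.51 and -0.54 in this comparison, with 0 of 28 and 0 of 25 called over all genes or adjusted over the list alone and adjusted p = 0.691 and 0.730 with an estimated correlation. Between the 2 untreated 48 h arrays themselves the medians were -0.19 and -0.12, with 22 of 28 and 21 of 25 members lower in spheres. The fit takes the difference between hours from treated and untreated arrays together. In spheres the list medians differed between hours by -1.12 and -1.87 with fenretinide, and by -0.06 and -0.17 without it. The fitted medians therefore hold part of a difference between treated arrays. Without the hour as a block, in a fit that sets unequal hours against each other, the mean of the G2/M list turned to 0.21 (adjusted p = 0.611). Of 18 stem cell markers 0 passed (2 higher and 2 lower adjusted over the list alone), and the list had a median of -0.01 (adjusted p = 0.768). Of 9 fibroblast genes tested only LUM passed, so that the median (-0.02) and mean (0.35) of that list had opposite signs (adjusted p = 0.768), as had those of apoptosis genes (-0.02 and 0.03) and oxidative phosphorylation (-0.00426 and 0.00586). The actin 3′ to 5′ difference was 0.229 larger in untreated spheres than in untreated adhered cells, and that of GAPDH 0.0417 larger. A variance trend gave 338 genes. A fit without the hour as a block, which sets unequal hours against each other, gave 564 (309 higher and 255 lower). The 4 untreated arrays alone gave 740 (412 higher and 328 lower). The fit of these 4 arrays also had no hour block, so it too set unequal hours against each other. It changed both the arrays and the block, so its count cannot be ascribed to either. Leaving out 1 array gave between 45 (6 higher and 39 lower, without the 48 h untreated adhered array) and 462 (without the 48 h untreated sphere array), with 80 without any other adhered array and 376 without any other sphere array.

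Interferon-induced genes also had the largest differences between hours in adhered cells, as the mean of untreated and treated arrays, although no gene passed. From 48 h to 72 h IFI44L was higher by 2.58 ± 0.24, IFITM1 by 1.98 ± 0.30, XAF1 by 1.63 ± 0.23, LAMP3 by 1.61 ± 0.31 and MX1 by 1.54 ± 0.20, each with adjusted p = 0.419. The untreated arrays carried the larger part: the difference was 3.10 in untreated and 2.07 in treated cells for IFI44L, 2.65 and 1.32 for IFITM1, 2.13 and 1.12 for XAF1, 2.24 and 0.98 for LAMP3, and 1.93 and 1.16 for MX1. AKAP12 had a difference of -1.12 ± 0.37 (with 3 other probe sets in the same direction but smaller, down to -0.24), DCAF17 of -0.999 ± 0.23, REXO5 of -0.93 ± 0.19, IL1RAP of -0.89 ± 0.15 and KRT13 of -0.81 ± 0.28. For AKAP12 it was -1.84 untreated and -0.40 treated, and for DCAF17 -0.56 and -1.44. Each of IFI44L, XAF1, LAMP3, AKAP12, DCAF17 and IL1RAP had at least 1 adhered array below the filter level, so the size of their differences depends on background, as it does in spheres for CENPE, ALDH5A1 and MAP2. By limma 0 of 13120 genes passed, with 1481 at an unadjusted p under 0.05. Interferon response genes as a list were higher at 72 h, with a median of 1.01 and 20 of 23 past the threshold adjusted over the list alone (adjusted p = 4.26e-22, and adjusted p = 0.561 with an estimated correlation). By fry neither this list nor any other passed between these hours, with a smallest adjusted p of 0.256. The list's median difference was 1.37 in untreated and 0.56 in treated cells. In spheres from 24 h to 48 h, again as the mean of untreated and treated arrays, the lowest values were those of the mitotic genes CENPE (-1.34 ± 0.43), KIF20A (-1.28 ± 0.44), DLGAP5 (-1.25 ± 0.45), NCAPG (-1.22 ± 0.44) and DEPDC1 (-1.19 ± 0.38), and the highest those of ALDH5A1 (1.10 ± 0.16), PLCB1 (1.08 ± 0.14), MAP2 (1.01 ± 0.45), NDRG1 (0.99 ± 0.17) and ABCG1 (0.94 ± 0.17). The treated arrays carried most of the difference for the mitotic genes and MAP2: it was -0.32 untreated and -2.37 treated for CENPE, -0.24 and -2.33 for KIF20A, and 0.13 and 1.88 for MAP2. Again 0 genes passed by limma, with 1444 at an unadjusted p under 0.05 and 384 past the threshold without either untreated sphere array. The G2/M and mitosis list had a median of -1.03 with 24 of 25 lower adjusted over the list alone, and the DNA replication list a median of -0.59 with 0 of 28, both with adjusted p = 0.890 with an estimated correlation. In untreated spheres the medians of these lists differed between hours by -0.17 and -0.06, and in treated spheres by -1.87 and -1.12. Without the treated 48 h sphere array, an alternative chosen after the data were seen, the mean of the DNA replication list was -0.06 (adjusted p = 0.178), and 1 list instead of 7 passed.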

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

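All tests of explanations in this part were chosen after the results they concern had been seen, and the split of the arrays likewise.

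Interferon response genes had lower levels in untreated spheres, and with fenretinide 20 of 23 fell in adhered cells while 10 of 23 rose in spheres, with 8 called in both. Counted with no test, 18 of 23 were higher and 5 lower in the 24 h sphere pair, and 19 and 4 in the 48 h pair. CMPK2, which is outside the list, was lower with fenretinide in both cultures. The median difference of effects was 1.91, no member passed the test of the difference over all genes, and the list had adjusted p = 0.634 with an estimated correlation. By fry it did not pass either, since the smallest adjusted p of any list was 0.142. The hour of sampling was excluded only as the whole cause, with 1 array per condition at the shared 48 h. At that hour the list's median differed by -2.00 between untreated spheres and untreated adhered cells. With the drug it changed by -0.94 in adhered cells and 0.52 in spheres, where HERC5, IFI44L, XAF1 and RSAD2 were below the filter level. From 48 h to 72 h the list's median difference was 1.37 in untreated and 0.56 in treated adhered cells. The hour can therefore still enter the size of the difference of effects. RNA integrity read from the actin probe sets, which shifted the same way in all 4 pairs, was excluded as the whole cause, since the list's median changed by -0.94 and -1.61 in the adhered pairs and by 0.56 and 0.52 in the sphere pairs. Culture, medium and dose stay open, because the design changes them together, and a raised interferon response in the adhered cultures that the drug lowers is a candidate explanation that was not tested.

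Fenretinide changed more genes at least 2-fold in spheres than in adhered cells. Of the explanations weighed, the 48 h treated sphere array alone stays open, since the 24 h sphere pair had 553 such genes against 237 and 390 in the adhered pairs, with 1 array per hour and no spread to set the excess against. RNA integrity stays open as well, since the actin 3′ to 5′ difference was larger by 0.145, 0.269, 0.439 and 0.496 in the order of the number of changed genes, while that of GAPDH was larger by 0.00996, 0.0487, 0.103 and 0.0307 and did not keep that order in the 48 h sphere pair, and the actin shift may follow the response as well as lead it. The difference in response size itself was not tested, and the sphere dose was the lower one. For the mean effect over both cultures, 1 of the 35 splits of the 8 arrays into 4 and 4 gave as many genes in a fit of 2 groups, the treatment split itself with 2595 genes, and the highest other split, that by culture, gave 212; the 8 splits that part every time-matched pair, of which the highest other gave 0, are too few for a share under 0.05.

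LUM was high in untreated spheres by a single probe set. The other LUM probe set differed by 0.17 at 48 h, so the signal may belong to that single probe set, although a probe set that detects LUM poorly would give the same value. Fibroblasts or their RNA in the spheres were excluded, since the 17 other genes of the fibroblast list differed by a median of -0.0300, from -0.404 to 0.265, with 0 over 1, while 9 of the 17 were at or below the filter level. The collagen gene COL1A1 was at 6.61 in untreated spheres and 6.59 in untreated adhered cells at 48 h, and SPARC at 2.86 and 2.96. No sort of the cultures is described in the labels.

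The effect of fenretinide differed between cultures by camera for 9 further lists, whose median difference, spheres minus adhered cells, was -1.06 for G2/M and mitosis, -1.16 for DNA replication, 0.14 for ER chaperones, 0.79 for ATF4 and CHOP targets, -0.32 for NRF2 targets, -0.27 for glycolysis, -0.59 for heat shock, 0.67 for metallothioneins and -0.33 for ribosome biogenesis. With an estimated correlation all of these lists had adjusted p = 0.634, and by fry none passed (smallest adjusted p of any list 0.142). In addition 16 genes passed in both cultures with opposite signs, although none passed the test of the difference (adjusted p from 0.0767 to 0.124). Of these, 8 belong to the interferon list, and 1316 of the 13120 genes tested had both adhered pairs on one side of 0 and both sphere pairs on the other. The difference of effects was 3.18 for IFIT1, 2.78 for DDX60, 2.77 for IFIT3, 1.96 for OAS1, 1.94 for IRF9, 1.91 for OASL, 1.66 for ISG15, 1.56 for IFI27, 1.49 for IRF7 and 1.48 for SAMD9. It was 2.07 for ALDH5A1, 0.89 for EIF2AK4, -2.21 for TUBA1A, -1.65 for UNKL, -1.56 for GLA and -1.03 for ASF1A.

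A separate fit held all 28939 probe sets above the filter level, with p-values adjusted over them. Among the 3665 of these that were not paired with a gene, 514 passed with fenretinide in adhered cells (429 higher and 85 lower) and 730 in spheres (423 higher and 307 lower). Of the other probe sets in that fit, 2660 and 7648 passed. The unpaired ones thus passed more often than the others in adhered cells and less often in spheres.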

How the results depend on the processing

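The gene lists without the treated 48 h sphere array were run after the data were seen, and all other alternatives were planned. The called genes named in the text and the called list members kept direction and threshold in 507 cases with quantile normalization (15 no longer passed), 506 with median centring (16), 491 with no filter (31), 520 with a variance trend (2), 401 without the hour block (121), 471 with only the arrays of the comparison (41) and 470 with a stricter filter, under which the others were no longer tested. Of the 1395 genes called in adhered cells 1186 passed with the stricter filter too. They did so in 471 cases with the mean of probe sets (49 no longer passed and 1 reversed), 363 with specific probe sets (23 and 2, the others having no such probe set that was tested) and 3137 over all arrays left out in turn (1039 no longer passed). At a single hour no called value turned, which the test requires for the drug effect within a culture. However, 122 values at 24 h, 171 at 48 h and 45 at 72 h lay farther from the reported value than its SE times the square root of 2. Among them was E2F8 in spheres (-1.81 at 24 h and -4.04 at 48 h against -2.93). Without the hour block, which for untreated spheres sets unequal hours against each other, 754 genes passed in adhered cells and 564 for untreated spheres, and with only the arrays of the comparison 2588 and 740. For untreated spheres 70 genes were higher and 94 lower as reported, but 309 and 255 without the block and 412 and 328 with only its arrays. For this comparison the fit of its arrays alone also had no hour block, so it too set unequal hours against each other. In adhered cells 724 genes rose and 671 fell as reported, but 687 and 764 with median centring, 653 and 703 with the mean of probe sets, 945 and 1087 with a variance trend, 845 and 916 with a stricter filter and 1112 and 1476 with only the adhered arrays, so the larger side changes. In spheres 2045 rose and 2325 fell as reported, but 2142 and 2133 with quantile normalization. Genes changed 2-fold at both sphere hours, with no test, were 300 higher and 197 lower. Every other alternative in spheres had more falls than rises. A variance trend gave 338 genes for untreated spheres and 40 for the difference, and no filter gave 14 for the difference. With a minimum of 2-fold 254 genes were left in adhered cells, 868 in spheres and 487 for the mean effect, and genes changed 2-fold at both hours with no test numbered 178, 497, 102 for the mean, 68 for the difference and 6 for adhered hours. Leaving out 1 array gave 18 to 2588 genes in adhered cells, 2061 to 3956 in spheres, 45 to 462 for untreated spheres, 0 to 695 for the difference, 2782 to 4975 for the mean, 0 for adhered hours and 0 to 384 for sphere hours. Either array of a pair gave the same value for the treatment effects, since the hour's effect is then fitted by the array left. A lone array is assumed to vary like the others. The culture of the array left out then adds nothing to the spread, which comes from the other culture alone. With an estimated correlation 0 lists passed in any of the 7 comparisons, in a test on 2 residual degrees of freedom that hardly any list could pass. With fry 1 passed in adhered cells, 5 in spheres and 0 for untreated spheres, the difference and both hours, while 12 passed for the mean. For sphere hours 4 lists passed with the mean of probe sets and 1 without the treated 48 h sphere array. Reversals were the G2/M list for untreated spheres without the hour block (0.21, adjusted p = 0.611), the oxidative phosphorylation list for sphere hours without that array (0.00935), GINS2 in spheres with specific probe sets (0.0399), and SC5D in spheres with the mean of probe sets (-0.0116) and with specific ones (-0.52). The GINS2 and SC5D reversals come from a second probe set. Without the treated 48 h sphere array, the difference between sphere hours is that of untreated spheres alone. There the median of the oxidative phosphorylation list was 0.04, against -0.16 in treated spheres. For the G2/M list the fit without the block compares unequal hours. The reported fit takes the hour difference from treated and untreated arrays together. In spheres that difference had a median of -1.87 treated and -0.17 untreated, so the reported value holds part of the treated arrays' difference. The untreated 48 h arrays themselves differed by a median of -0.125. How far the unequal hours account for the reversal was not tested. The only-arrays alternative has no value for the difference and the mean, nor the fit without an hour block for the hours. Signal over background is unknown for these arrays.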

Other observations

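The test of a shift toward the sphere profile was set out before its result was seen, though after the list results that prompted it, and the genes of the next paragraphs were picked from the fixed lists.

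Sphingolipid genes held single changes although the list did not pass in either culture (adjusted p = 0.401 and 0.485). Of 21 members 0 rose and 1 fell in adhered cells, and 5 rose and 3 fell in spheres (0 and 1, and 6 and 3, adjusted over the list alone). Over all 13120 genes tested, 10.6% passed in adhered cells and 33.3% in spheres. The counts of this list and of those below are to be read against these shares. DEGS2, a dihydroceramide desaturase gene, fell by 1.10 ± 0.09 in adhered cells and by 0.74 ± 0.09 in spheres with fenretinide, and was also lower in untreated spheres (-1.08 ± 0.12). DEGS1, the main desaturase gene, did not pass, at -0.12 and 0.16. In spheres the ceramidase genes ACER2 (1.45 ± 0.21) and ASAH1 (0.96 ± 0.13, with 0.20 by 1 of 3 other probe sets) rose, and the ceramide synthase gene CERS6 fell by 0.57 ± 0.11. None of these 5 genes passed the test of the difference between cultures.

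The stem cell marker list did not pass either (adjusted p = 0.297 and 0.276). Of its 18 members 3 rose and 4 fell in adhered cells, and 3 rose and 7 fell in spheres (3 and 6, and 3 and 7, adjusted over the list alone). KLF4 (1.33 ± 0.15 and 1.54 ± 0.15) and ALCAM (1.29 ± 0.22 and 1.83 ± 0.22) rose in adhered cells and spheres, SOX4 (0.72 ± 0.12) in adhered cells and ALDH1A3 (1.11 ± 0.24) in spheres, while 1 of 5 other SOX4 probe sets gave -0.45. Falls in both cultures were those of CD44 (-0.96 ± 0.15 and -1.30 ± 0.15, with 8 of 9 and 9 of 9 other probe sets in the same direction), ASCL2 (-1.18 ± 0.11 and -1.28 ± 0.11) and LRIG1 (-0.57 ± 0.13 and -0.74 ± 0.13, where another probe set gave 0.10 in spheres). LGR5 (-0.47 ± 0.11, another probe set -1.52) fell in adhered cells. ALDH1A1 (-1.61 ± 0.26, with -1.02 in the 24 h pair alone), CXCR4 (-1.56 ± 0.38), EPHB3 (-0.67 ± 0.10) and CD24 (-0.49 ± 0.09) fell in spheres.

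The p53 target list did not pass (adjusted p = 0.867 and 0.943). Of its 18 members 3 rose and 1 fell in adhered cells, and 5 rose and 4 fell in spheres (3 and 2, and 5 and 4, adjusted over the list alone). GDF15 (2.41 ± 0.13 in adhered cells and 2.39 ± 0.13 in spheres, another probe set 0.83 and 1.05), the cell cycle inhibitor CDKN1A (1.505 ± 0.20 and 0.92 ± 0.20, the latter with 0.498 in the 24 h pair alone) and the death receptor TNFRSF10B (0.68 ± 0.09 and 0.89 ± 0.09, with 0.21 by 1 of 2 other probe sets in spheres) rose in both cultures. FAS, another death receptor gene, fell by 1.29 ± 0.17 in spheres, and DDB2 fell by 0.77 ± 0.14. MDM2 did not pass, at -0.09 and -0.26. In the apoptosis list, which did not pass (adjusted p = 0.215 and 0.432), 2 of 22 rose and 0 fell in adhered cells, and 5 rose and 2 fell in spheres (the same counts adjusted over the list alone). PMAIP1, a BH3-only gene of apoptosis, rose by 0.56 ± 0.11 in adhered cells (another probe set 0.26) and by 1.14 ± 0.11 in spheres, and BMF, of the same class, rose by 0.99 ± 0.12 in spheres.

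Markers of differentiated colon cells went in both directions, and neither of their lists passed. Of 16 absorptive cell genes 2 rose and 2 fell in adhered cells (2 and 3 adjusted over the list alone; adjusted p = 0.550), and 3 rose and 2 fell in spheres (3 and 2 adjusted over the list alone; adjusted p = 0.640). KRT20 rose by 0.70 ± 0.11 in adhered cells, and DPP4 by 0.66 ± 0.13 and SLC26A2 by 0.92 ± 0.15 in spheres, where 1 of 2 other SLC26A2 probe sets gave 0.27. CEACAM5 rose by 0.70 ± 0.12 and 0.45 ± 0.12 (0.29 in the 24 h sphere pair alone), but a second probe set gave -0.29 and -0.14. The carbonic anhydrase gene CA2 fell by 1.52 ± 0.15 and by 0.94 ± 0.15 and the villin gene VIL1 fell by 1.13 ± 0.13 and by 0.58 ± 0.13, where other VIL1 probe sets gave values down to -0.28 in adhered cells. Of 13 goblet and related genes 1 rose and 2 fell in each culture (1 and 3, and 1 and 2, adjusted over the list alone; adjusted p = 0.492 and 0.816). AGR2 rose by 0.80 ± 0.11 and 1.08 ± 0.11, whereas REG4 fell by 1.94 ± 0.11 and by 2.31 ± 0.11, TFF1 by 0.61 ± 0.13 in adhered cells and TFF3 by 0.62 ± 0.17 in spheres.

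One hypothesis was that fenretinide moves adhered cells toward the sphere profile, since interferon genes were lower in both. Across genes, which are not independent replicates, the 72 h drug change in adhered cells and the difference of untreated spheres from adhered cells at 48 h had r = 0.185 (rho = 0.061). Without the interferon list r was 0.146, and without the genes called for untreated spheres as well r was 0.104 (rho = 0.048), between the bounds set for and against the hypothesis, so the test leaves it open. The drug change in spheres at 24 h gave r = -0.119.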
